A study of Homo sapiens with 9 samples.

How the data were processed

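Gene expression was measured by RNA sequencing in 9 libraries of KYSE410, an established human esophageal squamous cell carcinoma line. There were 3 libraries with a control shRNA (shcontrol), 3 with an shRNA against USP11 (shUSP11) and 3 with an shRNA against ARID1A (shARID1A). A short hairpin RNA lowers the messenger RNA it is directed against. Per the labels' protocols, cells were grown in RPMI-1640 with fetal bovine serum and total RNA was isolated with TRIzol. Groups were taken from the shRNA named in each label, and replicate numbers from the sample titles. How many hairpins were used per target, and whether the replicates were separate cultures, is not given in the sources used here. The p-values therefore measure only the spread between these libraries, which may be technical.

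Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p1 were used. The genome build, the annotation, the strand setting and any filter are not given in the sources used here. The authors deposited 1 table of FPKM values, meaning fragments per kilobase of gene length and per 1000000 reads assigned to the listed genes, for 19814 genes with numeric gene identifiers, symbols and a gene length. The deposited FPKM times length in kilobases summed to 1000000 in every library. Every positive value was a whole multiple, within 0.01 read, of what 1 read is worth in its library and gene, which gave the assigned reads per gene. Library totals were 34693342 to 36908848 assigned reads. Of the 28643 values of 1 to 12 reads, 66.2% were even, against 49.6% of the values above 100 reads, so both mates of a pair appear to have been counted mostly as separate reads. The number of independent fragments is then lower than the number of reads, and intervals from counts cover counting error only.

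FPKM values are not counts, so tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 11990. A linear model with 1 mean per group was fitted to all 9 libraries, with 6 residual degrees of freedom, and the variances were moderated with a trend on mean expression. The p-values are two-sided and were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are followed by their standard error (SE). Means of FPKM are given with the SD over 3 libraries. The comparisons were shUSP11 with shcontrol, shARID1A with shcontrol, and shARID1A with shUSP11.

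Replicate numbers were checked for pairing on the deviations of each library from its group mean. Libraries with the same number correlated at 0.185 to 0.568 across genes, and libraries with different numbers at -0.496 to 0.0317. Every same-number correlation was over 0.1, so the numbers were taken to pair the libraries, from the data and not from a label. A fit with the replicate number as a block has 4 residual degrees of freedom, and its values stand beside calls that it changes and beside counts whose total or larger direction it moves by over 1.5 times. No library was a copy of another. The chi-square per degree of freedom between replicates of a group was 21.4 to 93.5.

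There were 34 lists of genes, fixed in advance, and 29 of them had at least 5 tested members. They were tested with camera in limma at a preset correlation of 0.01 between genes, with a variance trend and adjustment over the 29 lists within each comparison. Camera with an estimated correlation and fry were run beside it. The estimated correlation rests on the 6 residual degrees of freedom, or 4 with the block, so that test has little power. A list that it does not call is not shown to be unchanged. Of the 15 genes of the list of mitochondrially encoded genes, 0 were in the table, so that list has no result. The genes named were set by a rule fixed in advance. It takes USP11, ARID1A, TRIM32 and SDC2, and the 8 largest rises and 8 largest falls per knockdown among called genes with a mean FPKM of at least 1 in the higher group and all 3 knockdown libraries beyond all 3 controls. It adds up to 4 called members with the largest change per list and comparison, or the 2 most abundant where none was called. It also adds 6 genes in each direction for both knockdowns and up to 4 with opposite changes, and 5 in each direction between the knockdowns. From these, genes were chosen for the text to illustrate each group, and 1 item that met the rule is not reported here.

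Alternatives set before the data were examined were another pseudocount (0.1), no filter or a filter at an FPKM of 5, median-of-ratios, upper-quartile, TPM and quantile scaling, limma without trend or with robust moderation, only the 6 libraries compared, the replicate block, each library left out in turn and a log2 fold change of at least 1. Alternatives added after seeing the data were limma voom on the recovered reads with and without the block, the libraries numbered 3 left out, the block with a correction for gene length and GC content, and the block with an estimated correlation in camera. GC content came from the longest transcript per gene in GENCODE v29, which gave a value for 98.7% of the tested genes.

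Both knockdowns share the 3 control libraries, which are too few to be divided between the comparisons. The overlap expected without any group difference was drawn 100 times in each way. The first reshuffled the 9 libraries of residuals, and the second, added after the first was seen, used random normal combinations of them, because a reshuffle can leave a group with no spread. A further set of 100, added later, combined the residuals of the blocked fit and was fitted with the block, because replicate effects cancel between the real groups but not in the other sets. On simulated data with 50 genes changed per fold, the test of shUSP11 against shcontrol on 11936 genes called 58% of the genes changed 1.5-fold, 74% of those changed 2-fold and 94% of those changed 4-fold. The corresponding values for shARID1A on 11922 genes were 52%, 80% and 98%. False calls were 5.33% of the calls for shUSP11 and 6.86% for shARID1A. The simulated genes varied independently of each other and had no effect of the replicate number. The real libraries have such an effect, so these rates need not hold for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.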

Results

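RNA sequencing compared KYSE410 esophageal squamous carcinoma cells carrying a control shRNA with cells carrying an shRNA against USP11, a deubiquitinating enzyme, or ARID1A, a subunit of the SWI/SNF chromatin remodelling complexes. The design asks which transcripts change with each knockdown and whether both knockdowns move the same genes. Each group had 3 libraries. Assigned reads were 34735488 to 35717708 in the shcontrol, 34693342 to 36424390 in the shUSP11 and 35165651 to 36908848 in the shARID1A libraries. Between 17183 and 17684 of the listed genes had an FPKM above 0 in a library.

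Each targeted gene was lower in all 3 of its knockdown libraries than in all 3 controls. USP11 was at 27.6 ± 0.419 FPKM in the shcontrol libraries and at 8.82 ± 1.27 FPKM in the shUSP11 libraries (SD, n = 3 each), a log2 fold change of -1.55 (SE 0.09, limma adjusted p = 8.2e-05). ARID1A was at 26.0, 26.3 and 23.6 FPKM in the shcontrol libraries and at 6.40, 6.59 and 5.95 FPKM in the shARID1A libraries, a log2 fold change of -1.85 (SE 0.07, limma adjusted p = 3.7e-06). Each target was also lower with the other shRNA. ARID1A was at 19.3 ± 0.599 FPKM (SD, n = 3) in the shUSP11 libraries and changed by -0.38 log2 (SE 0.07, limma adjusted p = 0.0051). With the replicate block the SE was 0.06, and after a further correction for gene length and GC content the change was -0.17 (SE 0.06) and no longer called (limma adjusted p = 0.0638). USP11 was at 20.2, 21.6 and 19.7 FPKM in the shARID1A libraries and changed by -0.41 log2 (SE 0.09, limma adjusted p = 0.0102).

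**Figure D1:**
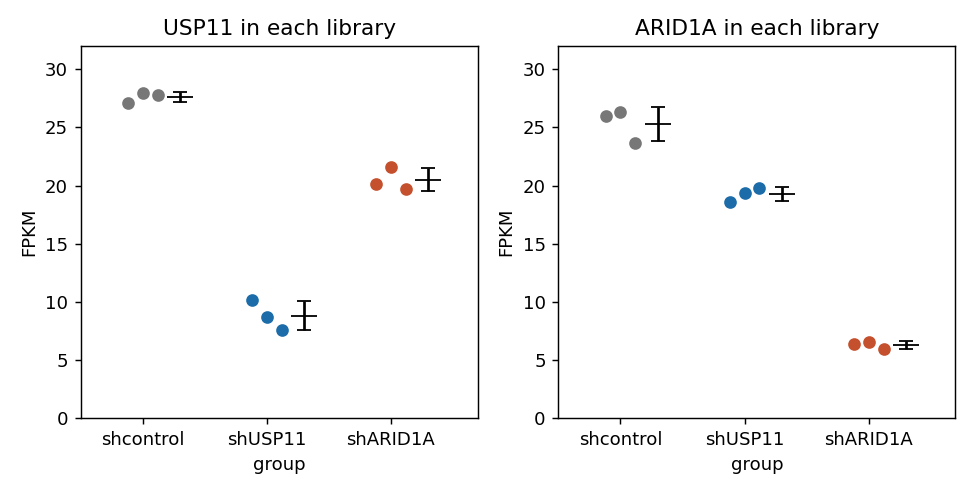
FPKM of USP11 (left) and ARID1A (right) in each of the 9 libraries by group, with points for libraries and a line with bars for the mean and SD of 3 libraries. The shUSP11 libraries have a mean of 8.82 FPKM for USP11, and the shARID1A libraries lie between 5.95 and 6.59 FPKM for ARID1A.

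The study's other named genes moved little or were near the floor. TRIM32, a ubiquitin ligase, was at 7.95 ± 0.514 FPKM in the shcontrol, 8.83 ± 0.865 FPKM in the shUSP11 and 7.75 ± 0.778 FPKM in the shARID1A libraries (SD, n = 3 each), and was not called in either knockdown (limma adjusted p = 0.34 and 0.819). SDC2, a heparan sulfate proteoglycan of the cell surface, was below the expression filter and was not tested. Its reads were 2, 2 and 2 in the shcontrol, 14, 14 and 8 in the shUSP11 and 2, 16 and 12 in the shARID1A libraries. All were even, and counted as pairs of mates they came to 3, 18 and 15 per group. The ratio to shcontrol was 5.96 (95% interval 1.74 to 31.6) for shUSP11 and 4.87 (95% interval 1.38 to 26.2) for shARID1A, by exact binomial limits that cover counting error only. In the shARID1A group, 1 library stayed at the control level.

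In the shUSP11 libraries, transcripts of inflammatory mediators were among the largest rises. PTX3, a secreted pattern recognition protein, rose from 5.59 ± 1.71 to 24.5 ± 5.18 FPKM (SD, n = 3 each), a log2 fold change of 1.96 (SE 0.27, limma adjusted p = 0.0015). The chemokine gene CXCL1 rose from 3.26 ± 0.731 to 11.5 ± 4.87 FPKM (SD, n = 3 each), CXCL8 by 1.47 log2 (SE 0.29), and BIRC3, an inhibitor of apoptosis, by 1.44 (SE 0.20). HAS2, a hyaluronan synthase, rose by 1.32 (SE 0.13) and CAPN8, a calpain protease, by 1.31 (SE 0.27). The largest fall among genes meeting the naming rule was that of AMTN, which encodes the enamel matrix protein amelotin, from 145 ± 38.2 to 30.8 ± 9.31 FPKM (log2 fold change -2.21, SE 0.24, limma adjusted p = 0.00067). CDKN2B, an inhibitor of cyclin-dependent kinases, changed by -1.86 (SE 0.26), KLHL24 by -1.75 (SE 0.22) and AHNAK2 by -1.67 (SE 0.21). CDKN2B, HAS2, PTX3, AHNAK2, KLHL24 and CAPN8 overlap other genes in the annotation, and the strand setting of the counting is not given in the sources used here. Genes of under 100 bases also met the rule (SNORD6, SNORD50B, MIR1281 and MIR4523). They rest on 0 to 79 reads per library and lie inside or beside longer genes, so their values are uncertain.

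Genes of cell division, protein synthesis and respiration rose together with the USP11 shRNA. Of 40 tested E2F targets and DNA replication genes, 27 rose and 0 fell (30 and 0 adjusted over the list alone), with a median of 0.39. The call was made at limma camera adjusted p = 9.44e-12 and was lost at adjusted p = 0.321 with an estimated correlation. GINS2 of the replicative helicase rose by 0.87 (SE 0.11), the sliding clamp PCNA by 0.72 (SE 0.12) and the ribonucleotide reductase subunit RRM2 by 0.67 (SE 0.07). Of 36 G2/M and mitosis genes, 27 rose and 0 fell (29 and 0 adjusted over the list alone), at limma camera adjusted p = 1.4e-10 and adjusted p = 0.4 with an estimated correlation. NUF2 of the kinetochore rose by 0.75 (SE 0.07), the mitotic kinase AURKB by 0.69 (SE 0.10) and CDK1 by 0.65 (SE 0.10). Of 42 ribosomal proteins, 36 rose and 0 fell (39 and 0 adjusted over the list alone), at limma camera adjusted p = 1.53e-18 and adjusted p = 0.321 with an estimated correlation. RPS12 rose by 0.66 (SE 0.07) and RPS19 by 0.63 (SE 0.06). Of 30 nuclear genes of the respiratory chain, 17 rose and 0 fell (21 and 0 adjusted over the list alone), at limma camera adjusted p = 6.48e-08 and adjusted p = 0.392 with an estimated correlation. NDUFA4 rose by 0.63 (SE 0.07).

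Further lists rose in the shUSP11 libraries. Of 31 MYC targets and ribosome biogenesis genes, 15 rose and 0 fell (18 and 0 adjusted over the list alone; limma camera adjusted p = 1.38e-06, and adjusted p = 0.4 with an estimated correlation), led by NME1 at 0.85 (SE 0.08). Of 20 NF-kB targets and inflammatory cytokines, 9 rose and 1 fell (10 and 1 adjusted over the list alone). That list had limma camera adjusted p = 0.00203, adjusted p = 0.4 with an estimated correlation and adjusted p = 0.0633 under the stricter expression filter. Of 29 homologous recombination and DNA damage genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone; limma camera adjusted p = 0.00534, and adjusted p = 0.402 with an estimated correlation). Of 17 antigen presentation genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone, 10 and 1 with the replicate block; limma camera adjusted p = 0.00916, and adjusted p = 0.467 with an estimated correlation), among them the immunoproteasome gene PSMB9 at 0.49 (SE 0.11) and CD47 at 0.54 (SE 0.07). The list also holds ligands that restrain immune cells, CD47 among them. Such ligands were most of its 4 called members with the largest change. Of 27 housekeeping genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone; limma camera adjusted p = 0.0147, and adjusted p = 0.321 with an estimated correlation), including PSMB4 at 0.53 (SE 0.07) and REEP5 at -0.93 (SE 0.07). Under the stricter expression filter the homologous recombination, antigen presentation and housekeeping lists were not called (limma camera adjusted p = 0.1, 0.127 and 0.0633), and quantile normalization gave 0.3 for the housekeeping list.

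Most tested histone genes and a part of the adhesion genes fell with the USP11 shRNA. Of 9 replication-dependent histones, 7 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.82 at limma camera adjusted p = 1.24e-05 and adjusted p = 0.321 with an estimated correlation. HIST1H2AC changed by -1.72 (SE 0.17) and HIST1H4H by -1.68 (SE 0.18). Members of this family are near copies of each other, so reads could be divided between them. Of 29 epithelial adhesion genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone, 14 and 2 with the replicate block), at limma camera adjusted p = 0.004 and adjusted p = 0.4 with an estimated correlation. The desmosomal genes DSG3 (-1.10, SE 0.18), DSP (-1.08, SE 0.14), DSC2 (-1.06, SE 0.15) and JUP (-0.82, SE 0.17) led the fall. Of 12 ABC drug transporters and related genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone), with ABCA1, a cholesterol exporter, at -1.38 (SE 0.21) and MVP at -1.37 (SE 0.22). That list had limma camera adjusted p = 0.0283, adjusted p = 0.467 with an estimated correlation, and adjusted p = 0.229 with the block and the length and GC correction. Without an expression filter it had limma camera adjusted p = 0.058, and under the stricter filter 0.163. Of 23 basal squamous and stemness markers, 4 fell and 2 rose, against 12 and 5 with the replicate block (limma camera adjusted p = 0.0769, 0.046 with the replicate block, 0.119 with the block and the length and GC correction, and 0.485 with the block and an estimated correlation). Of 28 hypoxia and glycolysis genes, 6 fell and 1 rose, against 10 and 3 with the replicate block (limma camera adjusted p = 0.0643, 0.046 with the replicate block, 0.0523 with the block and the length and GC correction, and 0.507 with the block and an estimated correlation). Of 22 syndecan, glypican and heparan sulfate synthesis genes, 4 rose and 0 fell, against 4 and 4 with the replicate block. Their median was -0.04 while the mean was 0.00 and the limma camera direction was up, at adjusted p = 0.774.

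Of 11990 genes tested, 3202 were called between shUSP11 and shcontrol, 1745 higher and 1457 lower, and 126 of them had a log2 fold change of at least 1 in size. The replicate block gave 5027 calls. TPM scaling put 38.5% of the calls on the higher side, against 54.5% with the deposited FPKM. Without shUSP11 replicate 2 the count was 1874 and without shUSP11 replicate 3 it was 2072.

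In the shARID1A libraries, CEACAM5, a cell surface glycoprotein, rose from 1.05 ± 0.633 to 16.3 ± 4.41 FPKM and FABP4, a fatty acid binding protein, from 64.7 ± 16.4 to 531 ± 149 FPKM (SD, n = 3 each). Their log2 fold changes were 3.09 (SE 0.31, limma adjusted p = 0.00041) and 3.01 (SE 0.30, limma adjusted p = 0.0004). CXCL8 rose by 2.79 (SE 0.29), CXCL1 by 2.38 (SE 0.25), PADI3, a peptidylarginine deiminase, by 2.26 (SE 0.28) and HAS3, a hyaluronan synthase, by 2.17 (SE 0.31). The calcium-binding gene S100A4 rose by 2.10 (SE 0.35) and the gap junction gene GJB2 by 2.03 (SE 0.44). KLHDC7B changed by -2.50 (SE 0.22), ERV3-1 by -2.34 (SE 0.15), SLFN5 by -2.20 (SE 0.18) and NDRG1 by -2.18 (SE 0.22). LCN2, the iron-binding protein lipocalin, went from 48.7 ± 13.5 to 10.2 ± 3.58 FPKM (SD, n = 3 each; log2 fold change -2.17, SE 0.32). C20orf24 varied between the shARID1A libraries, at 9.38 ± 6.84 FPKM (SD, n = 3), and changed by -2.21 (SE 0.34). KLHDC7B, ERV3-1, HAS3, C20orf24, S100A4, SLFN5, FABP4 and PADI3 each overlap other genes in the annotation, so their reads may be shared.

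The same proliferation, ribosomal and respiratory lists rose with the ARID1A shRNA. Of the E2F targets and DNA replication genes, 15 of 40 rose and 0 fell (19 and 0 adjusted over the list alone, 24 and 0 with the replicate block; limma camera adjusted p = 3.58e-07, and adjusted p = 0.535 with an estimated correlation). CCNE2, a cyclin of the G1/S transition, rose by 0.65 (SE 0.09), RRM2 by 0.58 (SE 0.07) and PCNA by 0.58 (SE 0.12). Of the G2/M and mitosis genes, 28 of 36 rose and 1 fell (29 and 1 adjusted over the list alone; limma camera adjusted p = 3.44e-10, and adjusted p = 0.535 with an estimated correlation), with CDK1 at 0.65 (SE 0.10) and MAD2L1 of the spindle checkpoint at 0.60 (SE 0.06). Of the ribosomal proteins, 33 of 42 rose and 0 fell (36 and 0 adjusted over the list alone; limma camera adjusted p = 1.09e-13, and adjusted p = 0.535 with an estimated correlation), with RPS3 at 0.46 (SE 0.07) and RPL9 at 0.45 (SE 0.06). Of the respiratory chain genes, 24 of 30 rose and 0 fell (25 and 1 adjusted over the list alone; limma camera adjusted p = 1.28e-12, and adjusted p = 0.523 with an estimated correlation), with NDUFA4 at 0.66 (SE 0.07) and SDHD at 0.62 (SE 0.08).

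The MYC target and ribosome biogenesis list had 12 rises and 1 fall in 31 genes (14 and 1 adjusted over the list alone; limma camera adjusted p = 0.000539, and adjusted p = 0.702 with an estimated correlation). Homologous recombination and DNA damage genes had 6 rises and 1 fall in 29 (6 and 1 adjusted over the list alone, 11 and 2 with the replicate block; limma camera adjusted p = 0.0204, and adjusted p = 0.666 with an estimated correlation). CHEK1, a kinase of the DNA damage checkpoint, rose by 0.43 (SE 0.07), and the list was not called without shARID1A replicate 2 (adjusted p = 0.0654) or under the stricter filter (adjusted p = 0.134). Housekeeping genes had 10 rises and 3 falls in 27 (12 and 4 adjusted over the list alone; limma camera adjusted p = 0.0136, and adjusted p = 0.523 with an estimated correlation), and were not called with the block and the length and GC correction (adjusted p = 0.103), under the stricter filter (0.0575) or with quantile normalization (0.428). Cholesterol and fatty acid synthesis genes had 5 rises and 0 falls in 32 (1 and 0 adjusted over the list alone, 10 and 0 with the replicate block), with a median of 0.30. This list had limma camera adjusted p = 0.00773 and adjusted p = 0.802 with an estimated correlation, and was not called without shcontrol replicate 1 (adjusted p = 0.0731) or shARID1A replicate 1 (adjusted p = 0.307), or by limma fry (adjusted p = 0.296). ELOVL6, a fatty acid elongase, rose by 0.55 (SE 0.11).

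Several lists held large changes without being called as lists in the shARID1A libraries. Of 31 NRF2 targets and glutathione genes, 10 fell and 2 rose, led by the ferritin gene FTH1 at -1.24 (SE 0.12), at limma camera adjusted p = 0.0553, adjusted p = 0.00944 with the replicate block and adjusted p = 0.591 with the block and an estimated correlation. Of 30 unfolded protein and ATF4 response genes, 9 fell and 6 rose (15 and 7 with the replicate block), with ASNS at -1.43 (SE 0.17) and CHAC1 at -1.78 (SE 0.38), at limma camera adjusted p = 0.198, adjusted p = 0.0432 with the replicate block and adjusted p = 0.698 with the block and an estimated correlation. Of 26 SWI/SNF subunits, 10 fell and 2 rose, including ARID1A itself and SMARCC1 at -0.73 (SE 0.09), at limma camera adjusted p = 0.144. Of 9 replication-dependent histones, 6 fell and 1 rose, at limma camera adjusted p = 0.0517, and at adjusted p = 0.0244 with the block and the length and GC correction. Of 23 basal squamous and stemness markers, 4 fell and 4 rose (9 and 7 with the replicate block), with KRT5 at -1.41 (SE 0.25) and KRT6A at -1.36 (SE 0.21), at limma camera adjusted p = 0.761. Of 29 epithelial adhesion genes, 7 fell and 2 rose (14 and 3 with the replicate block), with DSG3 at -1.14 (SE 0.18), at limma camera adjusted p = 0.144. The desmosomal falls were thus present with both shRNAs while the list was called with 1 of them, and its difference between the knockdowns had limma camera adjusted p = 0.175.

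Of 11990 genes, 3473 were called between shARID1A and shcontrol, 1690 higher and 1783 lower, and 196 of them had a log2 fold change of at least 1 in size. The replicate block gave 5279 calls. TPM scaling put 37.3% of the calls on the higher side, upper-quartile scaling 52.3%, quantile normalization 52.3% and median-of-ratios scaling 57.4%, against 48.7% with the deposited FPKM. Which direction held the majority thus depended on the scaling.

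**Figure D2:**
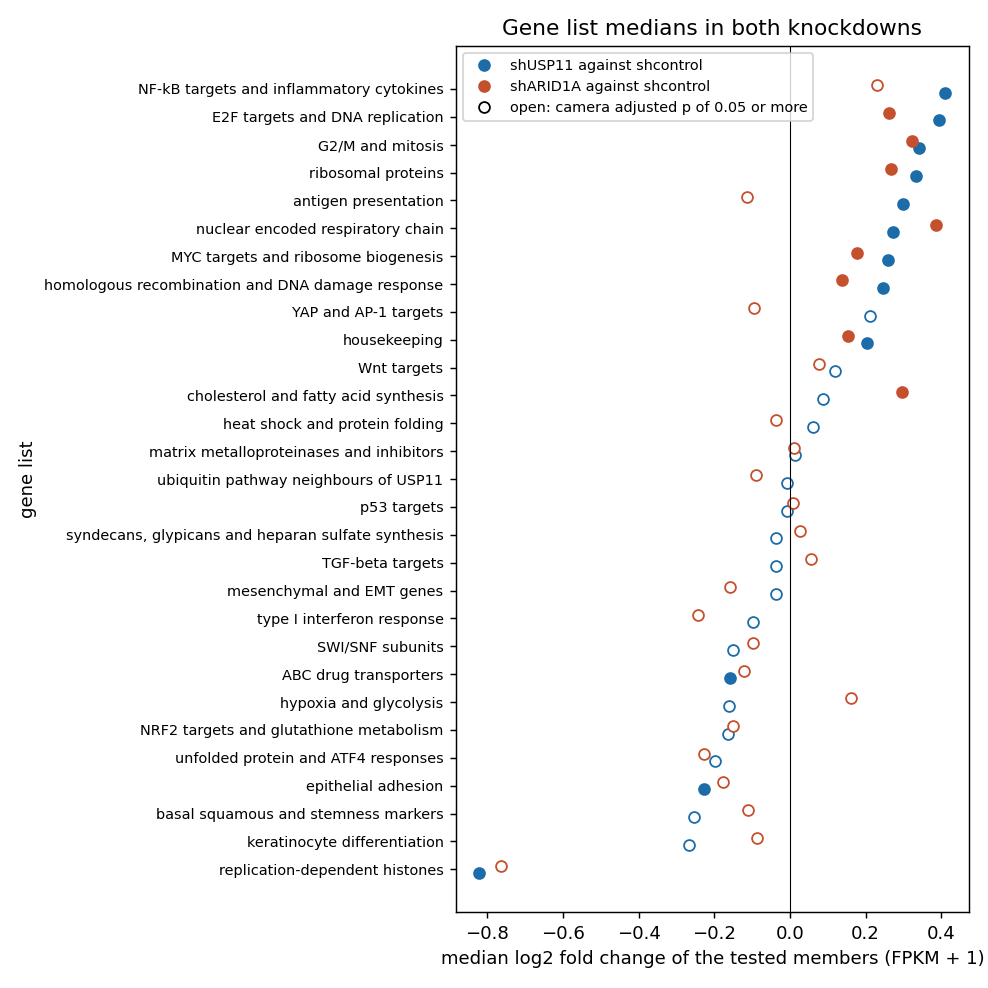
Median log2 fold change of FPKM + 1 over the tested members of 29 gene lists in shUSP11 (blue) and shARID1A (red) against shcontrol, with filled points for lists called by limma camera at the preset correlation and open points for the others. Ribosomal proteins lie at 0.33 and 0.27 (0.16 and 0.11 after correction for length and GC content) and replication-dependent histones at -0.82 and -0.76, and with an estimated correlation 0 lists were called in either comparison.

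Both knockdowns shared many changes. CXCL1, CXCL8 and STEAP1 were higher in both, STEAP1 by 1.28 (SE 0.19) in shUSP11 and by 1.91 (SE 0.19) in shARID1A. PNRC1 (-1.63, SE 0.18 and -1.64, SE 0.18), the amino acid transporter SLC7A8 (-1.63, SE 0.17 and -1.76, SE 0.17), NDRG1 (-1.62, SE 0.22 and -2.18, SE 0.22) and HIST1H4H (-1.68, SE 0.18 and -1.61, SE 0.18) were lower in both. In all, 1905 genes were called in the same direction, 1046 higher and 859 lower, and 48 in opposite directions. Independent lists would share 246 higher and 217 lower genes, and 465 in opposite directions. In 100 random combinations of the residual libraries, 0 genes were called in the same direction. All 9 libraries were drawn anew there with no group difference, and both comparisons shared the 3 drawn controls. Hardly any gene is called without a group difference, so this 0 sets no chance level for the 1905. Among 100 reshuffles of the residual libraries the median was 0 and the highest 446. The log2 fold changes correlated at 0.661 across genes, which are not independent replicates, against a median of 0.535 and a range of -0.788 to 0.977 in the random combinations. With residuals of the blocked fit the range was -0.948 to 0.944, so the correlation lies inside the range without a group difference either way. Their covariance was 0.0782 against a median of 0.00777 and a highest of 0.0725 in the random combinations, a difference of 0.0704 from the median, and the highest with residuals of the blocked fit was 0.0357. Part of the excess may come from the shared controls, which could not be split. Log2 fold changes also fell with gene length in both knockdowns (Spearman correlation -0.227 and -0.167), so part may come from that trend. The replicate block gave 3179 genes in the same direction and 184 in opposite directions, and without shUSP11 replicate 2 the first count was 1165. The count in opposite directions was 27 and 28 without shcontrol replicates 2 and 3, 23 and 25 without shUSP11 replicates 2 and 3, and 28 without shARID1A replicate 2.

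**Figure D3:**
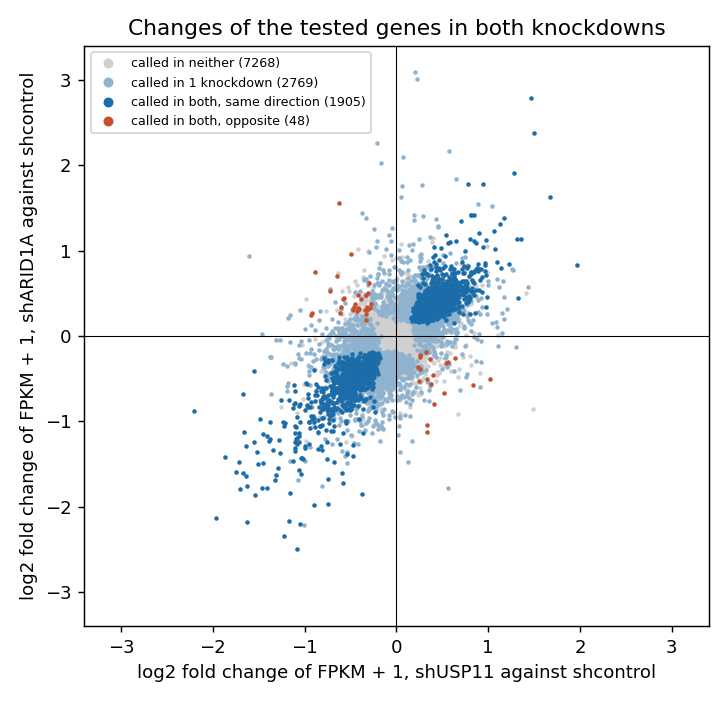
Log2 fold change of FPKM + 1 for each tested gene in shUSP11 (horizontal) and shARID1A (vertical) against the same shcontrol libraries, coloured by call. The 1905 genes called in the same direction fill the lower left and upper right, and the 48 called in opposite directions lie in the other quadrants among genes called in 1 knockdown or in neither.

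A direct comparison of the knockdowns, in which the controls enter only through the pooled variance, asked where they differ. CEACAM5 (2.89, SE 0.31), FABP4 (2.78, SE 0.30), PSCA (2.55, SE 0.40) and PADI3 (2.47, SE 0.28) were higher in shARID1A than in shUSP11. GJB2 was higher by 2.19 (SE 0.44), and was not called without shUSP11 replicate 2 (limma adjusted p = 0.0546). The elastase inhibitor PI3 was lower in shARID1A (-2.34, SE 0.25, limma adjusted p = 0.00075), as was RPSAP52 (-1.52, SE 0.13), which overlaps HMGA2. The receptor kinase AXL (-2.34, SE 0.49), the cytokine gene IL11 (-1.61, SE 0.37) and AKR1B10 (-1.59, SE 0.36) were also lower, but leaving out 1 library could end each of these calls. The highest limma adjusted p was 0.0709 for AXL without shUSP11 replicate 2, 0.0904 for IL11 without shUSP11 replicate 3 and 0.084 for AKR1B10 without shARID1A replicate 2. The cadherin gene CDH2 (-1.51, SE 0.24) and COL6A1 (-1.22, SE 0.14) were lower in shARID1A as well.

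Of 28 hypoxia and glycolysis genes, 4 were higher and 0 lower in shARID1A than in shUSP11 (9 and 1 adjusted over the list alone, 11 and 2 with the replicate block; limma camera adjusted p = 0.000501, and adjusted p = 0.836 with an estimated correlation), with ERO1A at 0.66 (SE 0.06) and PGAM1 at 0.48 (SE 0.06). Of 17 antigen presentation genes, 5 were lower and 0 higher (9 and 0 adjusted over the list alone, 8 and 0 with the replicate block; limma camera adjusted p = 0.000508, and adjusted p = 0.837 with an estimated correlation), with PSMB9 at -0.60 (SE 0.11). Respiratory chain genes had 1 higher, COX6A1 at 0.50 (SE 0.07), and 0 lower (1 and 0 adjusted over the list alone, 6 and 0 with the replicate block). That list had limma camera adjusted p = 0.00195, adjusted p = 0.837 with an estimated correlation and adjusted p = 0.265 by limma fry. Histones had 2 higher and 0 lower (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.00648, and adjusted p = 0.836 with an estimated correlation), with HIST1H2BK at 0.80 (SE 0.08). Cholesterol and fatty acid synthesis genes had 0 called (0 adjusted over the list alone, and 5 higher with the replicate block) and a median of 0.21, at limma camera adjusted p = 0.00232 and adjusted p = 0.837 with an estimated correlation, and adjusted p = 0.461 without shARID1A replicate 1 and 0.451 by limma fry. E2F targets had 4 lower and 0 higher (4 and 0 adjusted over the list alone, 10 and 0 with the replicate block; limma camera adjusted p = 0.0126, and adjusted p = 0.837 with an estimated correlation). They were not called without shUSP11 replicate 1 (adjusted p = 0.0634), shARID1A replicate 1 (adjusted p = 0.0792) or shARID1A replicate 3 (adjusted p = 0.0749), or by limma fry (adjusted p = 0.265). Ribosomal proteins had 5 lower and 1 higher (6 and 1 adjusted over the list alone, 8 and 1 with the replicate block; limma camera adjusted p = 0.00461, and adjusted p = 0.837 with an estimated correlation), and adjusted p = 0.108 without shARID1A replicate 2, 0.0771 with median-of-ratios scaling and 0.181 by limma fry.

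Between shARID1A and shUSP11, 1143 genes were called, 542 higher and 601 lower, and 106 of them had a log2 fold change of at least 1 in size. The replicate block gave 2652 calls. Median-of-ratios scaling put 59.6% of the calls on the higher side, against 47.4% with the deposited FPKM. The count was 739, 504 and 558 without shUSP11 replicates 1, 2 and 3, and 659 and 579 without shARID1A replicates 1 and 2.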

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

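The tests of the shared controls and of mixed RNA in this part were chosen after the results were seen, as was reading the replicate block, a fit set in advance, against the replication and mitosis lists, and so were the second simulation, the simulation with residuals of the blocked fit and the second condition of the mixing test.

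A difference between the knockdowns appeared in 48 genes called in opposite directions against shcontrol. All 48 were called in the direct test of shARID1A against shUSP11, which adds little, because genes chosen for opposite calls against the same controls differ by the sum of both changes. The count was 27 and 28 without shcontrol replicates 2 and 3, 23 and 25 without shUSP11 replicates 2 and 3, and 28 without shARID1A replicate 2, and it was 25 with only the 6 libraries compared and 184 with the replicate block. ELFN2 went from 2.89 ± 0.578 FPKM in shcontrol to 5.87 ± 0.438 in shUSP11 and 1.60 ± 0.195 in shARID1A (SD, n = 3 each), log2 fold changes of 0.83 (SE 0.12) and -0.57 (SE 0.12). HSPA2, a heat shock protein gene, changed by -0.65 (SE 0.15) and 0.71 (SE 0.15), but its fall was not called without shUSP11 replicate 3 (limma adjusted p = 0.0502). These genes stand against 1905 that moved the same way.

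The rise of ribosomal protein and respiratory chain genes and of replication and mitosis genes in both knockdowns was set against a trend with gene length and GC content. Log2 fold changes fell with length, at a Spearman correlation of -0.227 in shUSP11 and -0.167 in shARID1A, and the ribosomal protein genes are short. With both corrected in the blocked fit, the ribosomal medians went from 0.33 to 0.16 in shUSP11 and from 0.27 to 0.114 in shARID1A. The respiratory medians went from 0.27 to 0.19 and from 0.39 to 0.28. The smallest median of the replication and mitosis lists went from 0.26 to 0.253. Every limma camera adjusted p of these lists stayed under 0.05, so the trend as fitted may explain much of the ribosomal rise but not all of it. Quantile normalization alone gave ribosomal medians of 0.15 in shUSP11 and 0.11 in shARID1A. It was not combined with this correction, so whether both together would remove the ribosomal rise was not tested. With the replicate block the highest limma camera adjusted p of the replication and mitosis lists was 5.82e-08, but each group holds 1 library of each number, so the block cannot change these fold changes and the test decides nothing. The estimated correlation, which called 0 lists, leaves open whether co-regulation within each list could account for the calls, and a biological cause was not tested.

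The lower ARID1A in shUSP11 and the lower USP11 in shARID1A were set against mixed RNA and the same trend. RNA of shARID1A cells would have to make up 31.8% of the shUSP11 libraries, and 9 of 1142 genes called between the knockdowns lay below that share of their shARID1A level, such as CEACAM5 at 8.66%. In the other direction the share is 37.8%, with 10 genes below it, such as AXL at 11.8%. A limma treat test at these shares called 0 of 11990 genes in either direction, with 6 and 13 at an unadjusted p under 0.05, so mixing cannot be told apart from a change within cells. With length and GC content corrected in the blocked fit, the ARID1A change went from -0.38 (SE 0.06) to -0.17 (SE 0.06) and lost its call because the estimate shrank, so the trend may explain part of it, while the USP11 change stayed at -0.37 (SE 0.07) and called.

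The overlap of 1905 genes was set against chance values of the shared controls. Among 100 reshuffles of residuals the highest count was 446, but random combinations of residuals, with or without the block, gave 0 shared genes in all 100 sets, so these counts do not show how control values inflate an overlap among called genes. The covariance of 0.0782 was close to the highest of the random combinations, 0.0725, but above the highest with residuals of the blocked fit, 0.0357, whose median was 0.0056. The correlation of 0.661 lay inside both ranges. Shared controls alone gave a high correlation there (medians 0.535 and 0.582), so it cannot measure their share. No set without a group difference reached the observed covariance, but how much of the called overlap may come from the controls stays open. The trend with gene length also ran the same way in both knockdowns against shcontrol, at Spearman correlations of -0.227 and -0.167. Between the knockdowns it was 0.08. Such a shared trend can add to the overlap, and the overlap with the trend corrected is given with the processing alternatives below. A common effect of both shRNAs, such as a response to a hairpin that shcontrol lacks, was not tested.

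For each comparison, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes. The real counts were 3202, 3473 and 1143 for shUSP11 against shcontrol, shARID1A against shcontrol and shARID1A against shUSP11, and the highest other was 0 by limma in each. The other 9 splits had 73 to 1310, 129 to 950 and 82 to 1332 genes at an unadjusted p under 0.05. Of the splits, 4 part the 3 pairs of replicate numbers, and with the block the highest other among them was 0 as well. With 10 splits a share under 0.05 cannot be reached.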

How the results depend on the processing

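The voom fits, the libraries numbered 3 left out, the length and GC correction and the block with an estimated correlation were chosen after results were seen. USP11 in both knockdowns and ARID1A in shARID1A stayed called and lower under every alternative run for them. The fold threshold was not run for these genes, and USP11 in shARID1A is smaller than it. The USP11 change was -1.68 to -1.45 log2 in shUSP11 and -0.48 to -0.37 in shARID1A. ARID1A in shUSP11 was not called with the block and the length and GC correction, at -0.17. No called list turned direction under another scaling. The causes of the following moves were not tested, except that fewer libraries leave less power.

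Counts are given for shUSP11, shARID1A, the direct comparison and the same-direction overlap in turn, against 3202, 3473, 1143 and 1905. They were 5027, 5279, 2652 and 3179 with the replicate block, 5348, 5590, 3106 and 3413 with voom and the block, and 1994, 2042, 587 and 981 without the libraries numbered 3. With the block and the length and GC correction, shUSP11 had 4818, the direct comparison 3009 and the overlap 2942. The like setting for these is the block without the correction, at 5027, 2652 and 3179, so the correction lowered the overlap. A log2 fold change of at least 1 left 126, 196 and 106 genes. Leaving out 1 library at a time gave 1874 to 3176 for shUSP11, 504 to 1244 for the direct comparison and 1165 to 1627 for the overlap, each lowest without shUSP11 replicate 2.

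Of 29 lists, 12, 8 and 7 were called by limma camera. With an estimated correlation 0, 0 and 0 were called (4, 2 and 1 at an unadjusted p under 0.05), and with the block added 0, 0 and 0 (3, 1 and 1), while fry called 17, 10 and 3. Quantile normalization gave 13 for shARID1A. Beyond the values given above, the replicate block changed no other call of a list or targeted gene. The length and GC correction added to the block gave further calls by limma camera. In shUSP11 these were the NRF2, the unfolded protein and ATF4, and the YAP and AP-1 lists (adjusted p = 0.0414 each) and keratinocyte differentiation (0.0428). In shARID1A the type I interferon response was called (limma camera adjusted p = 0.0469), beside the histones.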

Other observations

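The test of the heat shock genes in this part, and the comparison of replicate numbers, were chosen after the data were seen.

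Libraries with the same replicate number shared expression changes across the 3 shRNA groups, with sizes that differed between the groups for some genes. Heat shock genes were higher in the libraries numbered 3 than in those numbered 1. HSPA6, an inducible chaperone of the HSP70 family, went from a mean of 0.978 to 35.1 FPKM (n = 3 each; log2 change 3.68, SE 0.50), HSPA1A rose by 2.12 (SE 0.27), and the metallothionein gene MT2A by 2.58 (SE 0.17). In the libraries numbered 3, HSPA6 was at 73.3 FPKM in shcontrol, 24.3 in shUSP11 and 7.59 in shARID1A. HSPA1A was at 305, 131 and 100 FPKM there, while MT2A was at 633, 414 and 735 FPKM. SERPINB3 (-2.20, SE 0.15), the water channel AQP3 (-1.95, SE 0.15) and the sodium channel subunit SCNN1A (-1.61, SE 0.09) fell. The libraries numbered 2 did not follow 1 pattern. Their means of HSPA6 and HSPA1A, 1.13 and 38.4 FPKM, were close to those of number 1. MT2A was already at 368 FPKM in number 2, against 96.8 and 594 FPKM in numbers 1 and 3. SERPINB3, AQP3 and SCNN1A also lay in between in number 2. From number 1 to number 3, 17 of 19 heat shock and protein folding genes rose and 0 fell, at limma camera adjusted p = 5.96e-17 and adjusted p = 0.584 with an estimated correlation. Unfolded protein and ATF4 response genes had 16 rises and 2 falls in 30 (limma camera adjusted p = 1.92e-08, and 0.584 with an estimated correlation). Mesenchymal and EMT genes had 13 rises and 2 falls in 21 (limma camera adjusted p = 9.69e-07, and 0.584 with an estimated correlation). Keratinocyte differentiation genes had 4 rises and 8 falls in 21 (limma camera adjusted p = 0.0275, and 0.584 with an estimated correlation), and TGF-beta targets 5 rises and 3 falls in 22 (limma camera adjusted p = 0.0293, and 0.584 with an estimated correlation). G2/M and mitosis genes had 4 rises and 0 falls in 36 (limma camera adjusted p = 5.77e-05, and 0.831 with an estimated correlation), and respiratory chain genes 0 rises and 6 falls in 30 (limma camera adjusted p = 0.0101, and 0.584 with an estimated correlation). Cholesterol and fatty acid synthesis genes had 0 rises and 8 falls in 32 (limma camera adjusted p = 9.00e-05, and 0.831 with an estimated correlation).

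For any difference among the replicate numbers, 1737 genes were called. The separate contrast of numbers 3 and 1 had 776 genes higher and 1378 lower in number 3. The median of the heat shock list in library 3 minus the mean of libraries 1 and 2 was 0.85 in shcontrol, 0.364 in shUSP11 and 0.38 in shARID1A, so the pattern was present in every group. This restates the pattern for which the list was chosen, and gives no separate evidence for a shared day or handling of libraries with the same number. The labels name neither.

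Markers of other cell types were mostly low. LUM, a matrix proteoglycan, was at 5.73, 12.1 and 22.3 FPKM in shcontrol, shUSP11 and shARID1A, FBLN1 at 47.1, 56.3 and 77.6 FPKM, and LCP1 at 34.1, 38.0 and 54.7 FPKM (means, n = 3 each). CD68 was at 19.6, 11.1 and 14.5 FPKM, COL1A1 at 3.03, 2.19 and 2.88 FPKM, GATA6 at 9.96, 10.5 and 8.07 FPKM, and PAX8 at 2.02, 1.97 and 1.72 FPKM. The means of CORO1A were 1.03, 1.31 and 1.62 FPKM and those of ESAM 0.803, 1.10 and 1.32 FPKM, so the means of 5 of these 9 markers were ordered shcontrol, shUSP11, shARID1A from low to high and 4 were not.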
